A study of Mus musculus with 6 samples.

How the data were processed

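Deposited FPKM values per gene were used as the authors gave them, for 6 libraries in 3 groups. The submitters' processing notes name bcl2fastq for base calling, HISAT2 2.0.5 for alignment and GRCm39 as the genome. The tool that computed FPKM, the annotation release and the use of strand in counting are not given in the sources used here. The labels' protocols name Trizol for RNA and standard Illumina protocols for libraries. Groups came from the sample titles and the genotype and treatment labels. The gene table held 55414 annotated genes and 295 unannotated transcripts, and the same 295 were listed with identical values in a table of their own. Unannotated transcripts were tested apart from genes. Coordinates are those of the deposited tables (GRCm39). The reference available here is GENCODE vM21 on GRCm38, and it was not used for coordinates, only for transcript sequences in the comparison of Gm7336 with Gapdh.

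Whether values came from whole fragments was checked with single-exon genes of 500 to 1500 bases. In each library, low values were multiplied by length less a trial offset and divided by a trial step. The step and offset kept had the largest share of whole multiples below 6 in excess of chance, with a tolerance of 0.03 beyond rounding. Between 417 and 458 genes were used, and 83.9% to 88.4% of them were whole multiples, where chance gives 17.3% to 19.0%. The step gave the implied number of fragments per library.

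Genes with a mean FPKM of 1 or more over the 6 libraries were tested, 11134 of the 22014 with a value above 0 in any library. A linear model of log2(FPKM + 0.5) with 3 group means was fitted to all 6 libraries in limma (version 3.58.1, lmFit, then eBayes with trend=TRUE). It had 3 residual and 3.46 prior degrees of freedom. The 3 comparisons were knockout on water against control on water, serine against water in knockouts, and knockout on serine against control on water. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. SE is the moderated standard error of the log2 fold change and SD that of the 2 libraries of a group. A gene was counted as non-overlapping where both libraries of 1 group lay above both of the other. Principal components used the tested genes, centred and not scaled. The tables used here hold FPKM rather than counts, so no count model was fitted.

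The design, the alternatives, the rule for named genes and 32 gene lists were fixed before the data were examined. The lists were written from textbook knowledge. They were glycolysis, gluconeogenesis and fasting hormone response, serine, glycine and one-carbon metabolism, the integrated stress response, endoplasmic reticulum chaperones, fatty acid oxidation and ketogenesis, fatty acid and triglyceride synthesis, cholesterol synthesis, amino acid catabolism and urea cycle, NRF2 targets and glutathione metabolism, the pentose phosphate pathway, and NADH shuttles, lactate and glycerol metabolism. Others were bile acid synthesis and transport, the acute phase response, p53 targets, the cell cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, the circadian clock, male-biased and female-biased liver genes, hepatocyte secreted proteins and interferon-stimulated genes. The rest were markers of cholangiocytes and progenitors, stellate cells and matrix, Kupffer cells and macrophages, lymphocytes and neutrophils, sinusoidal endothelium, blood, pancreas and adipose tissue, and pericentral and periportal hepatocytes. Each was tested with limma camera at the preset correlation of 0.01 (trend.var=TRUE), adjusted over the lists of a comparison. Beside it stood camera with an estimated correlation and limma fry. Members were counted at an adjusted p under 0.05 over all genes and adjusted over the list alone. Adjustment over the list alone does not correct for the number of lists or comparisons. With a median gene shift of 0.16, list medians of knockout on serine against control were given relative to the median of all genes.

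Genes named were Gapdh, and in each comparison the 8 higher and 8 lower genes with the largest absolute log2 fold change among those that passed. They had to have non-overlapping libraries, a mean FPKM of 5 or more in a compared group, and a symbol that was not a Gm number, a Rik clone or a pseudogene. Where none passed, the 8 with the smallest unadjusted p per direction were taken. Up to 4 members with the smallest p were named per list, with further members where they were called. Some genes that the rule selects are not reported here.

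The knockout change and the serine change share the knockout libraries on water. Their correlation and covariance were set beside 1000 simulated data sets with unchanged groups and the fitted spread. Calls were counted in 100 simulated fits of the same kind, in which at most 2 genes were called in the knockout and at most 1 of them in the opposite direction with serine.

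Alternatives were a pseudocount of 1 or 0.1, no filter, a filter at a mean of 5 FPKM, median-of-ratios or TPM scaling, the replicate number as a block, a fit of only the 4 libraries compared, robust variance moderation, no variance trend, and leaving out each library in turn. Median-of-ratios and TPM scaling were not run for unannotated transcripts, and the fit of 4 libraries was not run for the correlation or the genes moved back. In the fits without a library, the lone library of its group was assumed to vary like the other groups.

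The fit was tested on simulated data before use, in 50 data sets of 11134 genes with 200 changed in the knockout on water. It recovered 0.84% of changes of 0.50 on the log2 scale, 29.7% of changes of 1, 88.8% of changes of 2 and 97.4% of changes of 3. It made 114 calls on average, of which 4.72% were false. A list of 30 genes shifted by 0.50 was called in 50 of 50 data sets, and 1 of 1000 unshifted lists was called. The simulated genes varied independently, unlike real ones. Their variances were drawn from the fitted prior with normal noise, so the false share follows from the assumptions of the model. Changed genes were drawn from those with a mean log2(FPKM + 0.5) above 2, so recovery at lower levels was not tested.

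Analyses ran in R 4.3.3 with the package data.table (1.17.8), and figures in Python 3.11.15 with matplotlib 3.10.9. Seeds were fixed.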

Results

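Liver RNA was sequenced from 12-week-old male mice after 16 hours of fasting. The mice carried either a hepatocyte-specific deletion of Gapdh or the floxed genotype used as control. Gapdh encodes the glycolytic enzyme that oxidises glyceraldehyde 3-phosphate and forms NADH. Control mice drank plain water, and knockout mice drank plain water or water with 5% serine. Serine is an amino acid that cells can make from a glycolytic intermediate formed after the Gapdh step. Each of the 3 groups had 2 libraries, and each library was a pool of RNA from 2 mice. No control group on serine was analysed here, so whether serine acts differently in the knockout was not tested. The p-values measure the spread between pools of mice, not between single mice.

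The deposited FPKM values summed to between 787332 and 869451 per library. The steps between low values implied 17.3 M to 19.2 M fragments per library, with the deepest library 1.11 times the shallowest. Between 17480 and 17908 genes had a value above 0 in each library. The 10 most abundant genes took 21.3% to 25.8% of all FPKM. Mitochondrially encoded genes took 12.3% and 12.2% in the 2 control libraries. They took 9.70% and 12.6% in the knockout libraries on water, and 12.0% and 8.89% in those on serine. Across the 11134 genes tested, the libraries of a group correlated at 0.970, 0.967 and 0.965 for control, knockout on water and knockout on serine. The median gene differed between replicates by 0.21, 0.21 and 0.23 on the log2 scale.

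**Figure D1:**
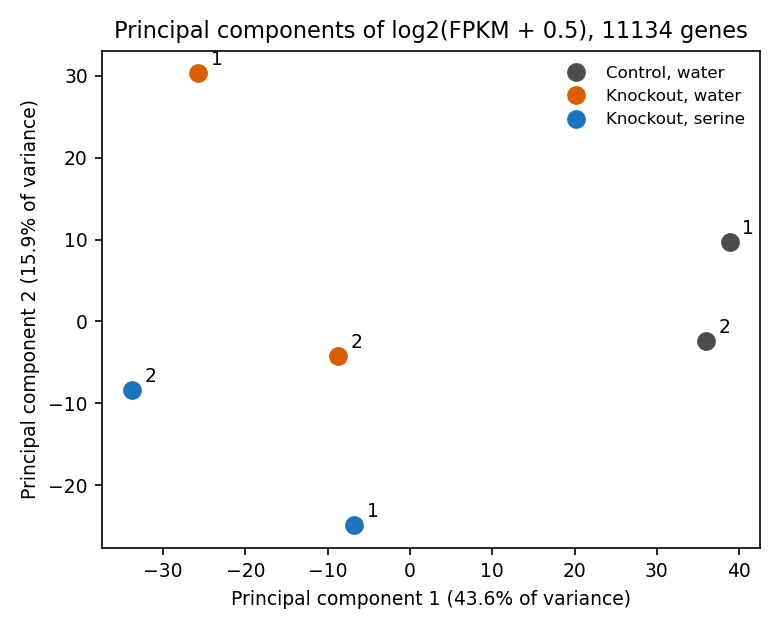
Principal component 1 (horizontal, 43.6% of the variance) and component 2 (vertical, 15.9%) of log2(FPKM + 0.5); each point is a library, coloured by group. The controls sit at 38.9 and 36.0 on component 1 and the 4 knockout libraries between -33.7 and -6.75, with the knockouts on water and on serine interleaved there. On component 2 the knockouts on water (30.3 and -4.27) lie above those on serine (-8.43 and -24.9), and the controls at 9.69 and -2.40.

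The deleted gene was measured first. Gapdh (ENSMUSG00000057666, chromosome 6, 125138678 to 125143430, minus strand, GRCm39) stood at 1091 and 1391 FPKM in the control libraries. It stood at 23.8 and 17.0 FPKM in the knockouts on water and at 20.0 and 23.5 FPKM in the knockouts on serine. The knockout means were 1.64% and 1.75% of the control mean. Gapdh fell by 5.90 on the log2 scale on water (SE 0.21, limma with Benjamini-Hochberg adjustment, adjusted p = 0.000352) and by 5.80 on serine (adjusted p = 0.000343). The fall passed in every alternative, with log2 values on water from -6.14 to -5.67.

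**Figure D2:**
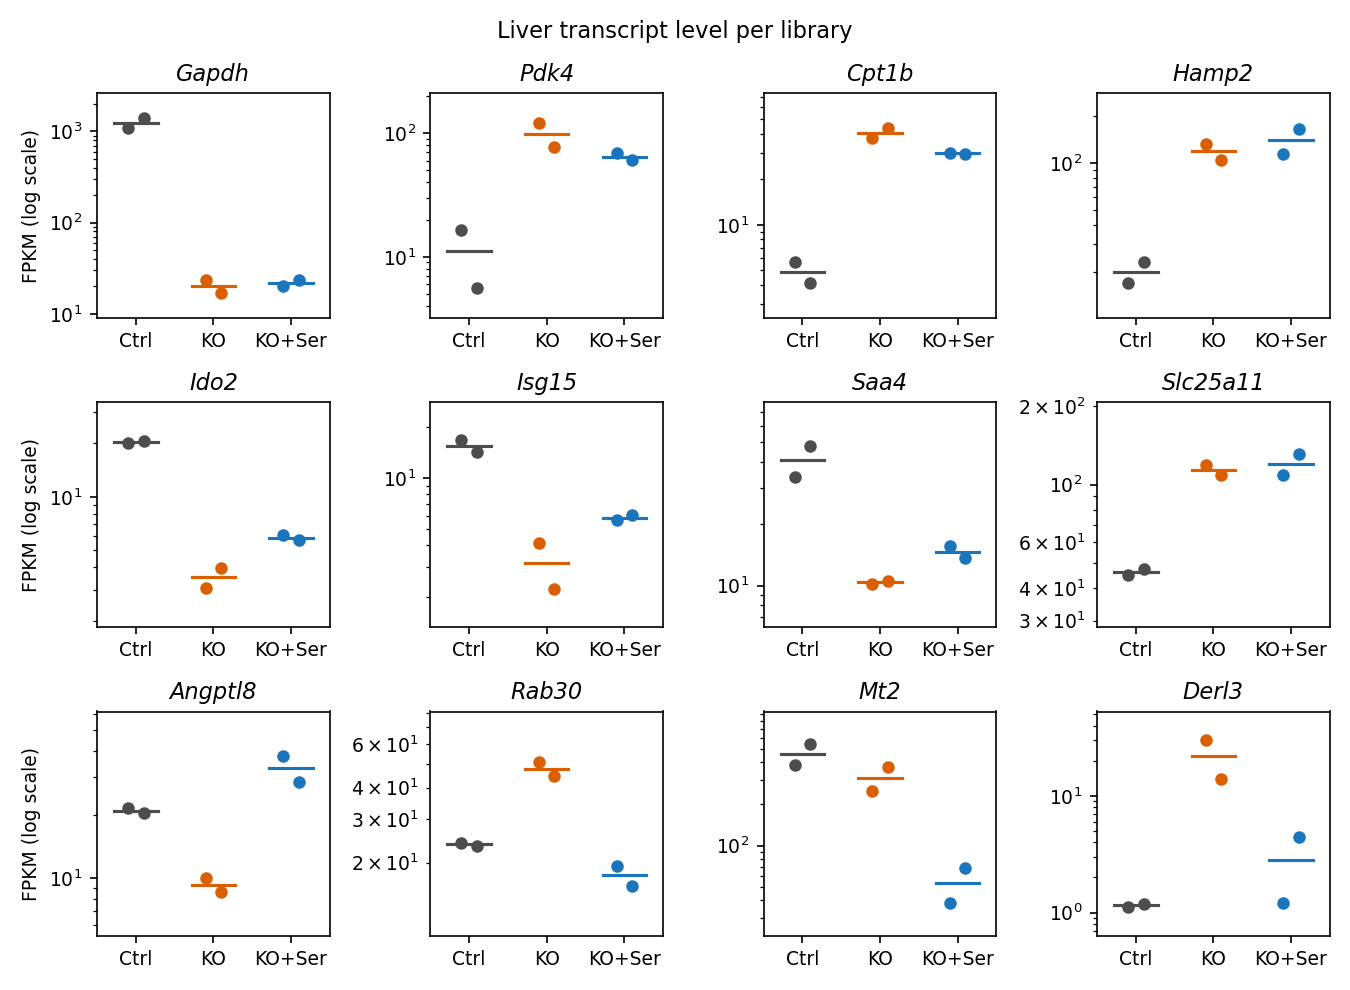
FPKM (vertical, log scale, a separate range per gene) of 12 genes in control (Ctrl), knockout on water (KO) and knockout on serine (KO+Ser); points are the 2 libraries of a group and the line is their mean. Gapdh falls from a control mean of 1241 FPKM to 20.4 and 21.8, while Angptl8 and Rab30 differ between the knockouts on serine and on water without passing the test.

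The first comparison set knockout on water against control on water, and asked what the fasted liver without hepatocyte Gapdh transcribes differently. Changes are given as log2 fold changes of FPKM + 0.5, which understates those of low genes, and levels as mean ± SD of 2 libraries. Pdk4, the kinase that switches off pyruvate dehydrogenase, rose from 11.1 ± 7.71 to 98.2 ± 30.5 FPKM (log2 change 3.24, SE 0.46, adjusted p = 0.0378). Cpt1b, the muscle form of the enzyme that lets long-chain fatty acids into mitochondria, rose from 4.88 ± 1.08 to 40.5 ± 4.48 FPKM (2.94, SE 0.18, adjusted p = 0.00652). The leptin receptor Lepr rose from 4.18 ± 3.46 to 45.0 ± 9.83 FPKM (3.50, SE 0.50, adjusted p = 0.0378). A pair of genes for glycogen-targeting subunits of protein phosphatase 1 moved in opposite directions. Ppp1r3g rose from 0.705 ± 0.0212 to 13.5 ± 2.98 FPKM (3.52, adjusted p = 0.0210), and Ppp1r3c fell from 32.9 ± 0.318 to 3.64 ± 1.84 FPKM (-3.09, adjusted p = 0.0482).

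Among the other named higher genes were Derl3, a factor of protein disposal from the endoplasmic reticulum (3.66, adjusted p = 0.0416), and Etnppl, the ethanolamine-phosphate phospho-lyase (2.91, adjusted p = 0.0422). AA986860 (2.76, adjusted p = 0.0478) and the hepcidin gene Hamp2 (2.55, adjusted p = 0.0210) also rose. Among the lower genes, Ido2, a tryptophan-degrading enzyme of the kynurenine route, fell from 20.3 ± 0.424 to 3.52 ± 0.658 FPKM (-2.38, SE 0.17, adjusted p = 0.0110). Isg15, an interferon-induced ubiquitin-like protein, fell from 15.4 ± 1.85 to 3.16 ± 1.34 FPKM (-2.17, adjusted p = 0.0317). The dehydrogenase family gene Sdr9c7 fell from 28.2 ± 1.36 to 6.74 ± 0.453 FPKM (-1.99, adjusted p = 0.0110). The serum amyloid gene Saa4 fell from 40.9 ± 10.1 to 10.4 ± 0.247 FPKM (-1.91, adjusted p = 0.0288). Hectd2os (-2.61, adjusted p = 0.0368) and the histone gene H3c15 (-2.44, adjusted p = 0.0472) fell as well. Hamp2 and H3c15 have near-identical relatives and Hectd2os is antisense by name, so their levels are uncertain. With median-of-ratios scaling, the calls of Derl3 (adjusted p = 0.0511), Etnppl (adjusted p = 0.0514), AA986860 (adjusted p = 0.0551), Ppp1r3c (adjusted p = 0.0511) and H3c15 (adjusted p = 0.0511) ended.

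In all, limma called 90 genes higher and 45 lower at a Benjamini-Hochberg adjusted p under 0.05, 77 and 41 of them by 2-fold or more. At an unadjusted p under 0.05 there were 2408 genes, against 557 expected by chance. Both knockout libraries lay on the same side of both controls for 55.4% of genes, where chance gives 33.3%. The share of calls that were higher was 66.7%, 56.0% with median-of-ratios scaling (61 higher, 48 lower) and 75.9% with TPM scaling (170 higher, 54 lower), which moved the median gene from 0.08 to 0.16. The count fell when a library of a compared group was left out. It was 4 higher and 3 lower without control replicate 1, 3 and 6 without control replicate 2, 11 and 3 without knockout water replicate 1, and 8 and 3 without knockout water replicate 2. It was higher, 117 and 97, without knockout serine replicate 1, and 116 and 99 without knockout serine replicate 2. Gapdh and the short gene model Gm43778 were called in all 4 fits that lacked a compared library and Cpt1b in 3, while 127 of the 135 genes were called in none.

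Genes of fatty acid oxidation and ketogenesis, which include targets of the fasting receptor PPAR alpha, were higher on balance in the knockouts on water. Of 45 genes tested, 9 rose and 0 fell over all genes, and 15 rose and 1 fell adjusted over the list alone. The median change was 0.17 (camera adjusted p = 0.0309), with adjusted p = 0.905 with an estimated correlation. Pex11a, which acts in peroxisome division (1.32), and the fatty acid transporter gene Slc27a1 (1.61) rose, each with adjusted p = 0.0306. Cyp4a31 (2.32) and Cyp4a32 (2.01) rose too, but resemble each other and may share reads. The list no longer passed without knockout water replicate 2 (adjusted p = 0.326), with the filter at 5 FPKM (adjusted p = 0.0675) or without the variance trend (adjusted p = 0.0519). Of 21 genes of gluconeogenesis and the fasting hormone response, 2 rose over all genes, and 7 rose and 1 fell adjusted over the list alone (median 0.35, camera adjusted p = 0.0424, and adjusted p = 0.677 with an estimated correlation). The 2 were Ppargc1a, the coactivator of fasting metabolism (1.57), and Igfbp1, a secreted binding protein for insulin-like growth factors (1.99), whose call ended with median-of-ratios scaling (adjusted p = 0.0591). This list did not pass without control replicate 2 (adjusted p = 0.147) or knockout water replicate 1 (adjusted p = 0.184). Nor did it with the filter at 5 FPKM (adjusted p = 0.0613) or without the variance trend (adjusted p = 0.0554).

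Glycolytic genes other than Gapdh were higher on balance. Of 20 tested, Eno1, the enolase (0.81), and Pgam1, a phosphoglycerate mutase (0.94), rose over all genes. With p adjusted over the list alone, 7 rose and 2 fell (median 0.47, camera adjusted p = 0.0361, and adjusted p = 0.490 with an estimated correlation). Both genes have processed copies in the genome, and with median-of-ratios scaling both calls ended (Eno1 adjusted p = 0.0587, Pgam1 adjusted p = 0.0606). The list call ended without control replicate 2 (adjusted p = 0.120), knockout water replicate 1 (adjusted p = 0.0673) or knockout water replicate 2 (adjusted p = 0.0505). It also ended with the filter at 5 FPKM (adjusted p = 0.0638) or without the variance trend (adjusted p = 0.0519). Of 31 genes of NADH shuttles, lactate and glycerol metabolism, Slc25a11, the mitochondrial oxoglutarate and malate carrier, rose from 46.1 ± 1.57 to 114 ± 6.78 FPKM (1.29, adjusted p = 0.0306), as did Pdk4. Adjusted over the list alone 7 rose and 2 fell, and the list as a whole did not pass (median -0.03, camera adjusted p = 0.820). The pentose phosphate list did not pass either, with 0 of 11 genes called over all genes and 1 adjusted over the list alone (median 0.18, camera adjusted p = 0.243).

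Nuclear genes of oxidative phosphorylation were higher almost throughout. Of 45 tested, 44 had a positive change and the median was 0.39 (camera adjusted p = 7.01e-09, and adjusted p = 0.590 with an estimated correlation). Cycs, which encodes cytochrome c, rose over all genes (1.15, SE 0.14, adjusted p = 0.0306), and 22 rose adjusted over the list alone. The 13 mitochondrially encoded mRNAs were lower on balance (median -0.34, camera adjusted p = 0.0136, and adjusted p = 0.905 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. mt-Cytb stood at -0.73, mt-Nd2 at -0.71 and mt-Nd1 at 0.47. The mitochondrial share of FPKM was lower in knockout water replicate 1 than in the other libraries on water. Without that replicate the mitochondrial list did not pass (adjusted p = 0.341), nor without control replicate 2 (adjusted p = 0.120). Cytosolic ribosomal protein genes were slightly higher, with 46 of 50 positive and a median of 0.20 (camera adjusted p = 0.000219, and adjusted p = 0.840 with an estimated correlation). None of them passed over all genes and 1 rose adjusted over the list alone. The ribosomal list did not pass without control replicate 1 (adjusted p = 0.0538) or knockout water replicate 2 (adjusted p = 0.0505).

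Interferon-stimulated genes fell together. Of 25 tested, 24 had a negative change, 6 fell over all genes and 16 fell adjusted over the list alone. The median change was -1.11 (camera adjusted p = 2.62e-13, and adjusted p = 0.104 with an estimated correlation). Isg15 fell, as did Ifit1, which binds foreign RNA (-1.95), and the interferon-inducible GTPase genes Irgm1 (-1.11) and Ifi47 (-1.47). With fry, which asks whether genes of a list move on balance in 1 direction without comparing them with other genes, the adjusted p was 0.00383. Genes of proteins that hepatocytes secrete were lower as well, with a negative change in 26 of 26 and a median of -0.37 (camera adjusted p = 4.78e-11, and adjusted p = 0.490 with an estimated correlation). Over all genes 0 of them passed, and 5 fell adjusted over the list alone, among them Fetub, fetuin B (-0.62), and Trf, transferrin (-0.82). The interferon, secreted protein and oxidative phosphorylation lists passed in all 6 fits with a library left out.

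The acute phase list did not move as a whole (median -0.14, camera adjusted p = 0.131), and its members went both ways. Of 26 genes, 2 rose and 2 fell over all genes, and 5 rose and 7 fell adjusted over the list alone. Saa4 and Fgg, the fibrinogen gamma chain (-1.20), fell, while Orm2, an orosomucoid gene with close relatives (1.94), and Il1rn, the interleukin 1 receptor antagonist (1.31), rose. Bile acid genes were lower on balance, with 0 of 23 called over all genes, and 1 higher and 6 lower adjusted over the list alone (median -0.17, camera adjusted p = 0.0102, and adjusted p = 0.677 with an estimated correlation). Nr0b2, the nuclear receptor known as SHP, had a value of -3.10 (adjusted p = 0.0523) and the bile salt export pump Abcb11 one of -1.60 (adjusted p = 0.107). The bile acid list did not pass without knockout water replicate 2 (adjusted p = 0.0783). Male-biased liver genes were lower (median -0.32, camera adjusted p = 0.00757, and adjusted p = 0.490 with an estimated correlation). Of 30 tested, Serpina1e (-1.61) and Mup20 (-1.15) fell over all genes, and 1 rose and 3 fell adjusted over the list alone. Both belong to families of near-identical genes. The male-biased list did not pass without control replicate 2 (adjusted p = 0.0859) or knockout water replicate 2 (adjusted p = 0.374).

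Targets of the integrated stress response, driven by the transcription factor ATF4, were higher on balance. Of 32 tested, Slc3a2, a subunit of amino acid transporters, rose (1.06), and the transcription factor gene Atf5 fell (-0.99). Adjusted over the list alone 3 rose and 1 fell (median 0.48, camera adjusted p = 0.00545, and adjusted p = 0.490 with an estimated correlation). The call ended without knockout water replicate 1 (adjusted p = 0.0641). Endoplasmic reticulum chaperone genes were higher in 19 of 22 (median 0.45, camera adjusted p = 0.0124, and adjusted p = 0.905 with an estimated correlation). Derl3 alone passed, both over all genes and adjusted over the list alone, while the chaperone Hspa5 had a value of 0.95. This list did not pass without control replicate 2 (adjusted p = 0.130) or knockout water replicate 1 (adjusted p = 0.362). Clock and clock-output genes had a median of 0.65 (camera adjusted p = 0.0467, and adjusted p = 0.490 with an estimated correlation). Of 19 clock genes, 0 passed over all genes and 6 rose adjusted over the list alone, among them Wee1 (1.53) and Usp2 (2.33). The clock list failed to pass in all 6 fits with a library left out, with adjusted p between 0.0562 and 0.0952. It also failed with TPM scaling (adjusted p = 0.144), the filter at 5 FPKM (adjusted p = 0.263), pseudocount 1 (adjusted p = 0.0502), no variance trend (adjusted p = 0.0519) or only the 4 libraries compared (adjusted p = 0.0595).

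Genes of serine, glycine and one-carbon metabolism did not move as a list in the knockouts on water (34 tested, median -0.05, camera adjusted p = 0.380). Over all genes 0 passed, and 2 rose and 4 fell adjusted over the list alone. Mat2a, which makes S-adenosylmethionine, had a value of 0.84, and Psat1, an enzyme of serine synthesis, one of 1.43. Amt, of the glycine cleavage system, had a value of -1.05 and Cbs, of transsulfuration, one of -0.81. Amino acid catabolism and urea cycle genes (40 tested) had 0 called over all genes, and 8 higher and 4 lower adjusted over the list alone (median 0.07, camera adjusted p = 0.959). Among 29 NRF2 targets and glutathione genes, heme oxygenase Hmox1 rose (1.32), and 2 rose and 3 fell adjusted over the list alone (median -0.09, camera adjusted p = 0.380). Cholesterol synthesis (median 0.26, camera adjusted p = 0.556) and fatty acid and triglyceride synthesis (median 0.09, camera adjusted p = 0.778) had 0 genes called over all genes. Of their genes 0 and 1 passed adjusted over the list alone. Of the 32 lists, 13 passed with the preset correlation, 0 with an estimated correlation and 3 with fry, the clock and glycolysis lists besides the interferon list. Median, mean and test differed in sign for 10 lists, none of them called.

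**Figure D3:**
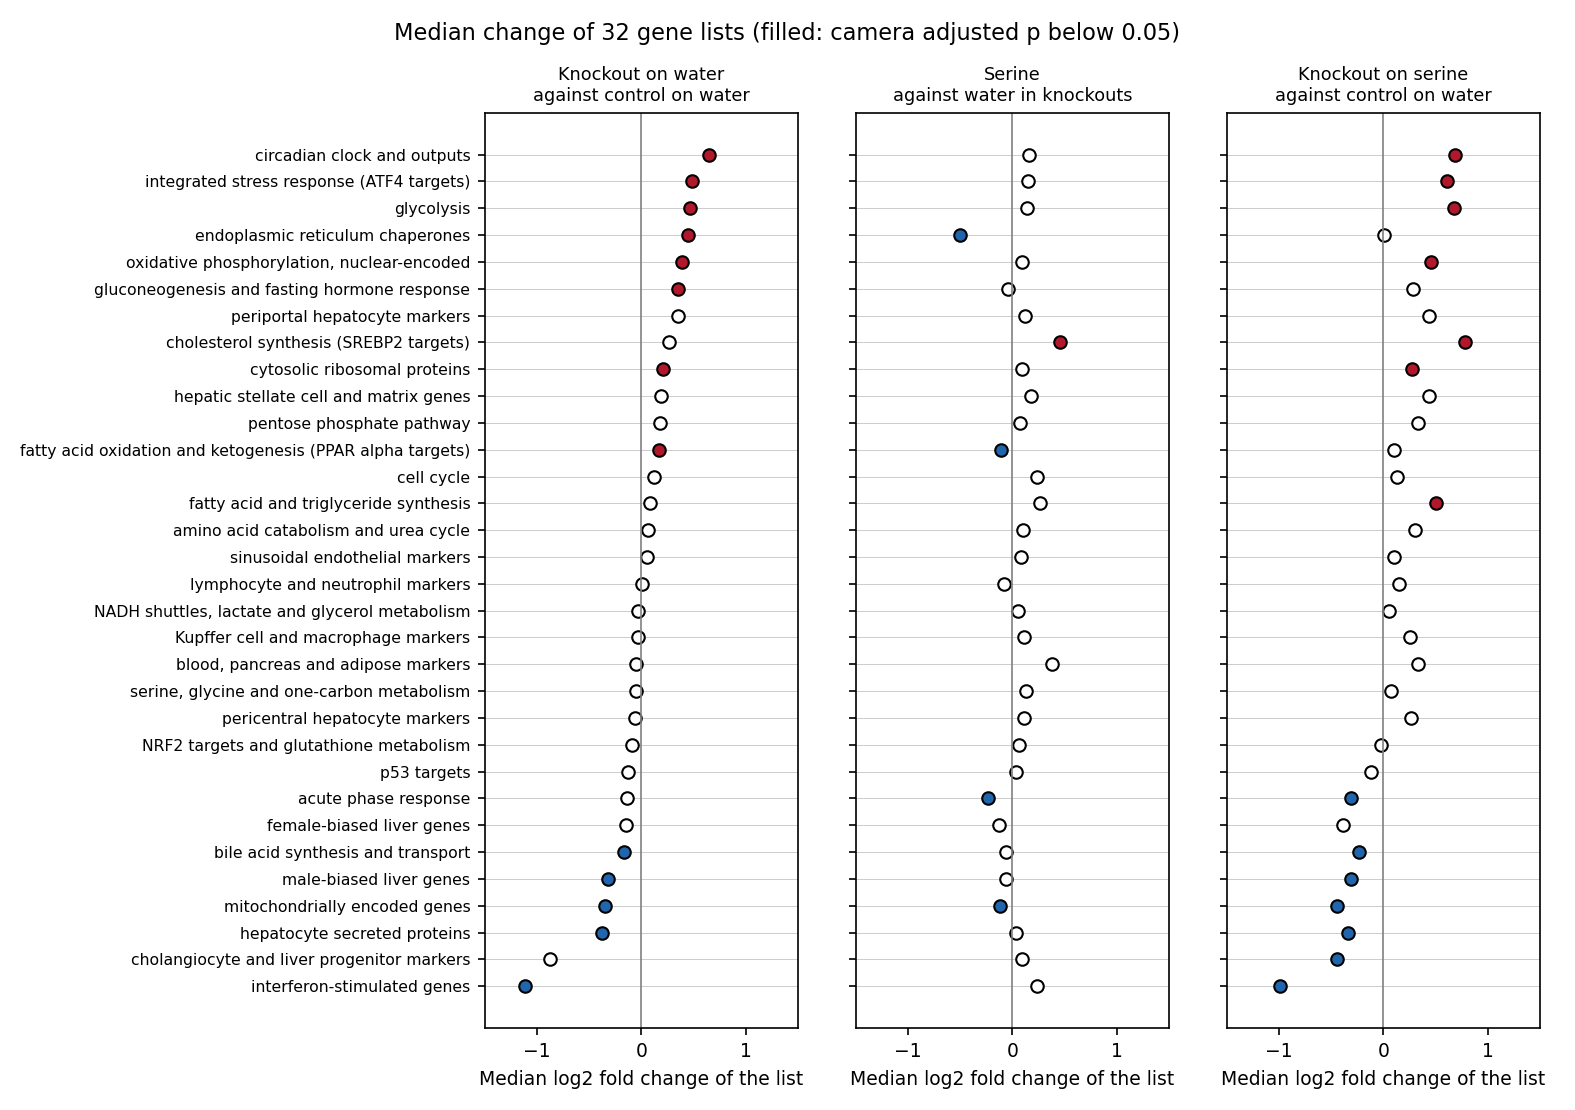
Median log2 fold change (horizontal) of 32 gene lists (vertical) in the 3 comparisons, 1 panel each; filled points have a camera adjusted p under 0.05 with the preset correlation, red for higher and blue for lower. Interferon-stimulated genes lie at -1.11 and -0.99 in the knockouts against control, and cholesterol synthesis at 0.46 with serine.

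The next comparison set serine against water in knockouts and asked what serine in the drinking water changed. In limma, 805 genes had an unadjusted p under 0.05 (578 higher, 227 lower) against 557 expected by chance. With median-of-ratios scaling 683 of 11143 genes did, and the median change of all genes went from 0.08 to 0.003. The surplus and its upward lean thus depend in part on scaling. No gene passed in limma, with a smallest adjusted p of 0.200. The genes with the smallest p are therefore given as values that did not pass. Angptl8, a feeding-induced inhibitor of lipoprotein lipase, stood at 9.32 ± 0.955 FPKM on water and 33.3 ± 6.63 on serine (log2 change 1.77, SE 0.18, adjusted p = 0.200), with controls at 20.9 ± 0.870. Rab30, a small GTPase of the Golgi, stood at 47.7 ± 4.57 and 17.8 ± 2.26 FPKM (-1.40, SE 0.15, adjusted p = 0.200), with controls at 23.7 ± 0.481. Atf5 stood at 239 ± 24.3 and 509 ± 45.9 FPKM (1.09, adjusted p = 0.374), with controls at 475 ± 46.1. Mt2, a metallothionein gene, stood at 307 ± 85.6 and 53.7 ± 22.0 FPKM (-2.54, adjusted p = 0.374), with controls at 464 ± 116. Derl3 stood at 21.9 ± 11.3 and 2.83 ± 2.29 FPKM (-2.84, adjusted p = 0.639), with controls at 1.16 ± 0.0495.

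The other genes named on the higher side were the splicing factor gene Isy1 (1.46), the transporter gene Abca8a (1.80), Sdr9c7 (0.88), Eps8l2 (0.76) and the histone gene H2bc4 (0.74). On the lower side were Rgs16, a regulator of G-protein signalling (-1.77), Orm2 (-1.30), the lysophospholipid transporter gene Mfsd2a (-0.93), the mitochondrial carrier gene Slc25a47 (-0.91) and C9orf72 (-0.82). The 2 serine libraries lay on the same side of both water libraries for 37.8% of genes, where chance gives 33.3%. Without knockout water replicate 1, 1 gene was called higher and 1 lower. Without knockout water replicate 2, 6 were called lower, and without knockout serine replicate 1, 3 were called higher. In the other fits, the scalings, filters and variance settings included, 0 were called.

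Cholesterol synthesis genes, targets of SREBP2, were higher with serine in 23 of 25 cases (median 0.46, camera adjusted p = 1.46e-05, and adjusted p = 0.960 with an estimated correlation). Over all genes 0 passed, and 4 rose adjusted over the list alone, among them the pathway enzyme genes Idi1 (1.31), Pmvk (0.66) and Sqle (1.15). The list did not pass without knockout serine replicate 1 (adjusted p = 0.116). Endoplasmic reticulum chaperone genes were lower with serine in 18 of 22 cases (median -0.50, camera adjusted p = 2.73e-10, and adjusted p = 0.960 with an estimated correlation). Only Derl3 fell adjusted over the list alone, while Sdf2l1 had a value of -1.69 and Hspa5 one of -1.08. Acute phase genes were lower (median -0.23, camera adjusted p = 2.90e-06, and adjusted p = 0.960 with an estimated correlation), with Orm2 alone passing adjusted over the list alone. Fatty acid oxidation genes were lower in 30 of 45 cases (median -0.11, camera adjusted p = 6.14e-06, and adjusted p = 0.960 with an estimated correlation), with 0 passing adjusted over the list alone and Cyp4a32 at -1.13. That list did not pass without knockout serine replicate 2 (adjusted p = 0.406). With fry, 0 lists passed, with a smallest adjusted p of 0.555.

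The mitochondrially encoded list was lower with serine (median -0.12, camera adjusted p = 0.0372, and adjusted p = 0.968 with an estimated correlation), with 0 of 13 members passing either way. Its call ended without either control replicate (adjusted p = 0.0676 and 0.0675) or without knockout water replicate 2 (adjusted p = 0.910). It also ended without a filter (adjusted p = 0.173), without the variance trend (adjusted p = 0.0553) or with only the 4 libraries compared (adjusted p = 0.0696). It turned upward, uncalled, without knockout serine replicate 2 (adjusted p = 0.927), the library with the lowest mitochondrial share. Genes of serine, glycine and one-carbon metabolism were higher in 26 of 34 cases, but the list did not pass (median 0.13, camera adjusted p = 0.277). The median of all genes with serine against water was itself 0.08. Adjusted over the list alone, which does not correct for the number of lists, Amt was higher (0.92) and Sdsl, a serine dehydratase homologue, lower (-0.67). The integrated stress response list did not pass (median 0.16, camera adjusted p = 0.667), with Atf5 alone higher adjusted over the list alone, nor did interferon-stimulated genes (median 0.24, camera adjusted p = 0.320) or nuclear oxidative phosphorylation genes (median 0.10, camera adjusted p = 0.277). The interferon list passed as higher with the filter at 5 FPKM (adjusted p = 0.0181), and the oxidative phosphorylation list without a filter (adjusted p = 0.0235). Over all 32 lists, 5 passed and 27 did not. Median, mean and test differed in sign for 8 lists, none of them called.

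Some lists that did not pass in serine against water in knockouts passed when a library was left out. Without knockout water replicate 2, the gluconeogenesis (adjusted p = 0.0279), p53 (adjusted p = 0.0489), male-biased (adjusted p = 0.00126) and female-biased (adjusted p = 0.0377) lists were lower. In the same fit the ribosomal list (adjusted p = 0.0377) and the blood, pancreas and adipose list (adjusted p = 4.75e-06) were higher. Without knockout serine replicate 2, the fatty acid and triglyceride synthesis (adjusted p = 5.62e-05), stellate cell (adjusted p = 0.0472) and blood (adjusted p = 0.0422) lists were higher and the gluconeogenesis list lower (adjusted p = 0.0422). Without knockout serine replicate 1, amino acid catabolism was higher (adjusted p = 0.000444) and bile acid genes lower (adjusted p = 0.00194). Without knockout water replicate 1, integrated stress response genes were higher (adjusted p = 0.0456). Fatty acid and triglyceride synthesis genes, with all libraries, had a median of 0.27 (camera adjusted p = 0.0656), and passed with median-of-ratios (adjusted p = 0.0434) and TPM scaling (adjusted p = 0.0387) and without a filter (adjusted p = 0.0179). With the filter at 5 FPKM, the gluconeogenesis and p53 lists passed as lower (adjusted p = 0.0397 for each).

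The last comparison set knockout on serine against control on water. Etnppl rose from 69.6 ± 25.6 to 759 ± 398 FPKM (3.38, SE 0.44, adjusted p = 0.0370), and Car2, a carbonic anhydrase gene, from 2.19 ± 0.361 to 15.7 ± 0.0636 FPKM (2.60, SE 0.17, adjusted p = 0.00800). Nupr1, a stress-induced nuclear protein gene, rose from 0.730 ± 0.0141 to 8.21 ± 3.72 FPKM (2.76, adjusted p = 0.0485). Mt2 fell to 53.7 ± 22.0 FPKM (-3.14, SE 0.34, adjusted p = 0.0350), and Fga, the fibrinogen alpha chain, from 2401 ± 74.7 to 691 ± 225 FPKM (-1.83, adjusted p = 0.0370). Also higher were Ly6d (3.44), Ppp1r3g (2.95), AA986860 (2.87), Hamp2 (2.78) and the transcription factor gene Olig1 (2.73). Also lower were Hectd2os (-2.50), the ion channel family gene Asic5 (-2.29), the interferon-induced Ifit3 (-1.82), Ido2 (-1.70) and Mug1, a murinoglobulin (-1.70). Ifit3 and Mug1 have close relatives, and their levels are uncertain. With median-of-ratios scaling, the calls of Ly6d (adjusted p = 0.0689), Etnppl (adjusted p = 0.0529), AA986860 (adjusted p = 0.0688), Nupr1 (adjusted p = 0.0688) and Hectd2os (adjusted p = 0.0529) ended.

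Here limma called 95 genes higher and 36 lower, 73 and 36 of them by 2-fold or more, with 2866 genes at an unadjusted p under 0.05. Both serine libraries lay on the same side of both controls for 57.0% of genes, where chance gives 33.3%. The median gene was 0.16 higher on the log2 scale, and 0.01 higher after median-of-ratios scaling. The share of calls that were higher was 72.5%, 44.4% with median-of-ratios scaling (16 higher, 20 lower) and 84.9% with TPM scaling (327 higher, 58 lower). Leaving out control replicate 1 gave 2 higher and 3 lower, and leaving out control replicate 2 gave 2 and 6. The count was 1 and 3 without either knockout water replicate. It was 129 and 74 without knockout serine replicate 1, and 2 and 2 without knockout serine replicate 2. Gapdh and Gm43778 were called in all 4 fits that lacked a compared library, and 56 of the 131 genes in none.

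Cholesterol synthesis genes had a positive change in 25 of 25 in the knockout on serine against control on water, with a median 0.62 above that of all genes (camera adjusted p = 0.000443, and adjusted p = 0.540 with an estimated correlation). Over all genes 1 rose, and 13 rose adjusted over the list alone, among them Lss (1.35) and Fdps (1.43), enzymes of the pathway. The call ended without knockout serine replicate 1 (adjusted p = 0.0761). Fatty acid and triglyceride synthesis lay 0.34 above all genes (camera adjusted p = 0.0489, and adjusted p = 0.638 with an estimated correlation), with 0 of 24 called over all genes and 3 higher adjusted over the list alone, among them Acly (0.90). This call ended without control replicate 1 (adjusted p = 0.210), knockout serine replicate 1 (adjusted p = 0.695), knockout water replicate 1 (adjusted p = 0.0538) or knockout water replicate 2 (adjusted p = 0.0543). It also ended with the filter at 5 FPKM (adjusted p = 0.146), without the variance trend (adjusted p = 0.0750) or with only the 4 libraries compared (adjusted p = 0.0530). Fatty acid oxidation did not pass (camera adjusted p = 0.802). Of its genes Slc27a1 rose (1.33) over all genes, a call that ended with median-of-ratios scaling (adjusted p = 0.0688), and 10 rose adjusted over the list alone, while Pdk4 had a value of 2.67.

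Nuclear oxidative phosphorylation genes lay 0.29 above all genes (camera adjusted p = 2.66e-09, and adjusted p = 0.450 with an estimated correlation). Of 45, 5 rose over all genes, Cycs (1.25), Ndufc2 (1.01), Ndufa8 (0.84), Uqcrc1 (0.81) and Ndufb10 (0.75), and 29 rose adjusted over the list alone. With median-of-ratios scaling, the calls of Ndufc2 (adjusted p = 0.0774), Ndufa8 (adjusted p = 0.0786) and Uqcrc1 (adjusted p = 0.0810) ended. Ribosomal protein genes lay 0.11 above all genes (camera adjusted p = 5.78e-05, and adjusted p = 0.638 with an estimated correlation), with Rpl3 higher over all genes (0.88) and 3 adjusted over the list alone. Glycolytic genes lay 0.51 above all genes (camera adjusted p = 0.0318, and adjusted p = 0.377 with an estimated correlation). Eno1 (0.97) and Pgam1 (1.12) rose again, and 10 rose and 2 fell adjusted over the list alone. That call in the knockout on serine against control on water ended without control replicate 2 (adjusted p = 0.0677), without knockout serine replicate 1 (adjusted p = 0.0698) or with the filter at 5 FPKM (adjusted p = 0.0555). Among NADH shuttle genes, Slc25a11 (1.36) and the malate dehydrogenase gene Mdh2 (0.76) rose, and 8 rose and 1 fell adjusted over the list alone, without a list call (camera adjusted p = 0.906). The same scaling ended the calls of Eno1 (adjusted p = 0.0659), Pgam1 (adjusted p = 0.0688), Rpl3 (adjusted p = 0.0777) and Mdh2 (adjusted p = 0.0774). Integrated stress response genes lay 0.45 above all genes (camera adjusted p = 0.00252, and adjusted p = 0.377 with an estimated correlation). Slc3a2 (1.17) and Nupr1 rose over all genes, and 11 rose and 1 fell adjusted over the list alone. Clock genes lay 0.53 above all genes (camera adjusted p = 0.0377, and adjusted p = 0.377 with an estimated correlation), with 1 higher over all genes and 9 higher adjusted over the list alone, Usp2 (2.64) among them. The clock call ended without knockout serine replicate 1 (adjusted p = 0.111) or either knockout water replicate (adjusted p = 0.0515). It also ended with the filter at 5 FPKM (adjusted p = 0.273), TPM scaling (adjusted p = 0.0525) or only the 4 libraries compared (adjusted p = 0.0522).

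Lists that were lower in the knockout on serine against control on water included interferon-stimulated genes, with a median of -1.15 relative to all genes (camera adjusted p = 9.14e-12, and adjusted p = 0.129 with an estimated correlation). Ifit3, Ifit1 (-2.04) and Ifi47 (-1.30) fell over all genes, and 11 fell adjusted over the list alone. Hepatocyte secreted protein genes lay at -0.51 relative to all genes (camera adjusted p = 2.60e-12, and adjusted p = 0.377 with an estimated correlation), with 0 of 26 called over all genes and 9 lower adjusted over the list alone. Acute phase genes lay at -0.48 relative to all genes (camera adjusted p = 5.28e-05, and adjusted p = 0.377 with an estimated correlation). The fibrinogen genes Fga, Fgb (-1.68) and Fgg (-1.54) and Saa4 (-1.43) fell, and Il1rn rose (1.22). Of the acute phase genes, 1 rose and 7 fell adjusted over the list alone. Bile acid genes lay at -0.40 (camera adjusted p = 5.28e-05, and adjusted p = 0.413 with an estimated correlation), with 0 of 23 called over all genes and 1 lower adjusted over the list alone. Male-biased genes lay at -0.47 (camera adjusted p = 5.78e-05, and adjusted p = 0.377 with an estimated correlation). Elovl3, a fatty acid elongase gene, rose (0.99) and Mup20 fell (-1.09), and 2 rose and 5 fell adjusted over the list alone. Median-of-ratios scaling ended the calls of Elovl3 (adjusted p = 0.0548), and of Mup20, Saa4 and Ifi47 (adjusted p = 0.0529 for each).

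The 13 mitochondrially encoded mRNAs lay at -0.61 relative to all genes in the knockout on serine against control on water (camera adjusted p = 5.78e-05, and adjusted p = 0.615 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. Cholangiocyte and progenitor markers lay at -0.61 too (6 tested, camera adjusted p = 0.0377, and adjusted p = 0.377 with an estimated correlation). Sox9, a transcription factor of bile duct cells, fell (-1.85), and 1 rose and 2 fell adjusted over the list alone. The Sox9 call ended with median-of-ratios scaling (adjusted p = 0.0548). The list call ended with that scaling (adjusted p = 0.112), without a filter (adjusted p = 0.0515), without control replicate 2 (adjusted p = 0.0574) or knockout serine replicate 2 (adjusted p = 0.124). Serine, glycine and one-carbon genes did not pass as a list (camera adjusted p = 0.720), with 0 called over all genes, and 6 higher and 1 lower adjusted over the list alone, among them Psat1 (1.85). Gluconeogenesis (camera adjusted p = 0.179), endoplasmic reticulum chaperones (0.172), amino acid catabolism (0.455), NRF2 targets (0.218) and the pentose phosphate pathway (0.272) did not pass. Of these, Nr4a1 (2.32) and Ppargc1a (1.54) rose, Fkbp5 fell (-1.59) and Hmox1 rose (1.26). These 4 calls ended with median-of-ratios scaling (adjusted p = 0.0688, 0.0688, 0.0529 and 0.0696). Without a filter, gluconeogenesis (adjusted p = 0.0296) and the pentose phosphate pathway (adjusted p = 0.0452) passed as higher. Without knockout serine replicate 2 the chaperone list passed as lower (adjusted p = 2.82e-06) and the fatty acid oxidation list as higher (adjusted p = 0.0101). Without knockout serine replicate 1 amino acid catabolism passed as higher (adjusted p = 0.0148) and NRF2 targets as lower (adjusted p = 0.0414). In all 14 lists passed, of which 0 passed with an estimated correlation and 5 with fry. The pentose phosphate pathway also passed with fry, as higher (fry adjusted p = 0.0342). Its median was 0.33 and that of all genes 0.16, a shift that fry does not take out. Median, mean and test differed in sign for 6 lists, none of them called.

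The design also lets the knockout change be set against the serine change gene by gene. Of the 90 genes higher in the knockout on water, 63 had a negative serine change, with a median of -0.19. Of the 45 lower genes, 35 had a positive one, with a median of 0.42. The genes were chosen by their values in the same knockout libraries on water, so a lean of this kind arises without any effect of serine, and its size was not simulated. Examples among the higher genes are Derl3, Orm2 and Rab30, and among the lower ones Atf5, Ppp1r3c and Angptl8. None of the 135 was called in either direction with serine, in limma or in any alternative that kept all libraries. In some fits without a library, genes were called back, but they were counted among the knockout calls of that fit, not among the 135. Without a knockout library on water, the lone one left enters both changes with opposite sign. Calls back can then arise without any effect of serine. On serine against control, 47 of the 90 were still called higher, where independent lists would share 0.768, and 18 of the 45 still lower, where they would share 0.146. Both comparisons use the same controls, so independence is not the value without change. In 100 simulated fits of unchanged groups at most 1 call was shared, but at most 2 genes were called there in the knockout on water. That shared count was bound to be small and is no reference for the overlap. A knockout change with noise from shared controls was not simulated. With 2 control libraries the controls could not be split, and part of this overlap may come from them. Across genes, the knockout change and the serine change correlated at -0.33. Both contain the knockout libraries on water with opposite sign, and 1000 simulated data sets with unchanged groups gave -0.50 ± 0.03 (SD). The covariance was -0.0698 against -0.0466 ± 0.00373 (SD) in the simulation, a difference of -0.0232. The correlation was thus less negative than simulated and the covariance more negative. Simulated genes varied independently, unlike real ones. The correlation was -0.0998 without knockout serine replicate 1 and -0.554 without knockout water replicate 2. Genes are not independent replicates, and no p was computed over them.

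**Figure D4:**
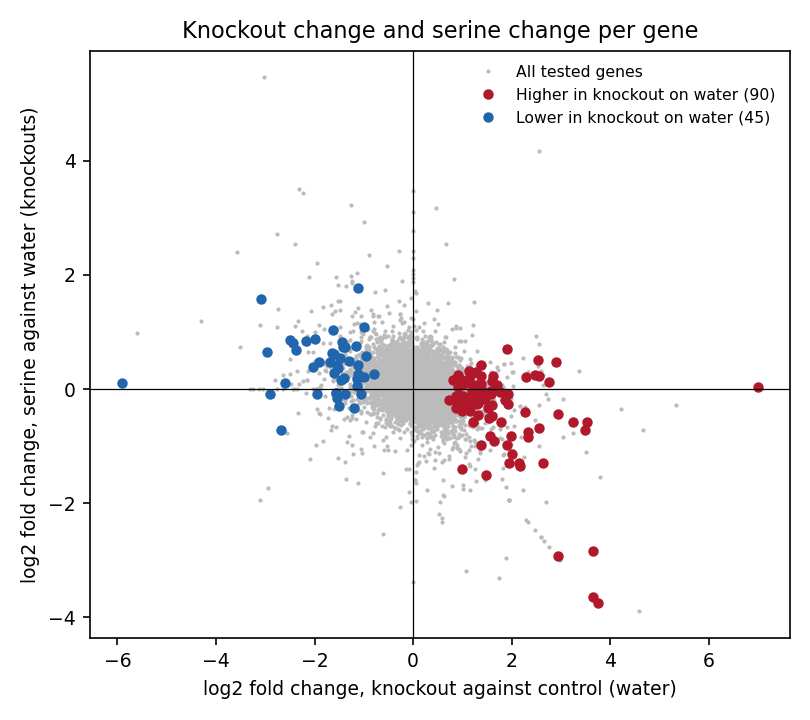
Log2 fold change of knockout on water against control on water (horizontal) and of serine against water in knockouts (vertical); each point is a gene, with the 90 called higher and 45 called lower in the knockout on water in colour. Of the 90, 63 lie below 0 on the vertical axis, and of the 45, 35 lie above it.

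Unannotated transcripts were deposited with coordinates but no gene name, and the 188 with a mean of 1 FPKM or more were tested on their own. In the knockout on water against control, 13 were higher and 4 lower, on serine against control 5 and 4, and with serine against water 0 (10 at an unadjusted p under 0.05 in limma). A transcript with a large change was on chromosome 13, 55332115 to 55337052, minus strand, between genes and 15543 bases from Fgfr4, a growth factor receptor gene that also senses intestinal hormone signals. It stood at 25.6 and 22.8 FPKM in controls, 1401 and 423 in knockouts on water and 351 and 1227 in knockouts on serine (4.96, SE 0.79, adjusted p = 0.0361 on water). Another on chromosome 11, 86702517 to 86707820, plus strand, 3945 bases from Dhx40, stood at 420 and 283, then 1344 and 1001, then 701 and 886 FPKM (1.75, adjusted p = 0.0361 on water). Both overlap a transcript on the opposite strand, and strand use in counting is not given in the sources used here. A transcript on JH584297.1 was listed at 0 in both controls and at 104 and 27.0 FPKM in knockouts on water. Counts were unstable when a library was left out. In the knockout on water, 4 were called without control replicate 1, 0 without control replicate 2, 1 without knockout water replicate 1, 3 without knockout water replicate 2 and 0 without either knockout serine replicate. On serine against control, 1 or 2 were called in each such fit, and with serine against water 0 to 2.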

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

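With 2 pools per group, call counts depended on the settings, while called changes kept their sign. Of 411 pairs of named gene and comparison, 0 with a call were reversed in any alternative, and 19 of 6508 values, all uncalled, changed sign. This lack of reversals was largely fixed in advance and says little about robustness. The genes with the largest changes were named only with non-overlapping libraries, so leaving out a library could not reverse them. The filters, variance settings, block and fit of 4 libraries leave the log2 change as it was. Gapdh kept its call throughout. Without a filter on low values, the knockout on water had 1 gene higher and 1 lower (90 and 45 as reported), and the knockout on serine 2 and 1 (95 and 36 as reported). With the filter at 5 FPKM, the counts were 133 and 62 on water and 372 and 78 on serine. The filter changes both the genes adjusted over, 22014 without it and 7262 at 5 FPKM (11134 as reported), and the variance fit, and their parts were not separated. Without the variance trend, the counts were 10 and 6 on water and 4 and 4 on serine. With robust variance moderation they were 135 and 70 on water and 216 and 60 on serine. TPM scaling gave 170 higher on water, and 327 and 58 on serine; median-of-ratios scaling gave 16 and 20 on serine. A fit of only the 4 libraries compared gave 98 lower on water, and 1 and 3 on serine. For the other settings the cause was not tested.

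Leaving out each library in turn, the knockout on water had 3 to 117 genes higher and 3 to 99 lower, serine against water in knockouts 0 to 3 and 0 to 6, and the knockout on serine against control 1 to 129 and 2 to 74. These fits have fewer samples, and the lone library was assumed to vary like the other groups. List calls, 13, 5 and 14 in the 3 comparisons as reported, ran from 7 to 12, from 4 to 10 and from 12 to 16. With an estimated correlation they were 0, 0 and 0, and with fry 3, 0 and 6. With the filter at 5 FPKM, serine against water in knockouts had 8 lists. The correlation of the knockout and serine changes (-0.33) ran from -0.554 to -0.0998, and the genes moved back with serine (0 as reported) from 0 to 5, with 1 without knockout serine replicate 1 and 2 without knockout water replicate 1.

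Unannotated transcripts changed, 17, 0 and 9 as reported, ran from 0 to 4, from 0 to 2 and from 1 to 2 when a library was left out. In the knockout on water 3 were called without a filter, 4 without the variance trend and 0 with only the 4 libraries compared. Serine against water in knockouts had 1 without the trend and 1 with only the 4 libraries, and the knockout on serine 1 with only the 4 libraries.

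Replicate numbers recur across groups, but replicate differences correlated at only 0.0281, 0.0387 and -0.197 between groups, so the numbers need not pair libraries. With the number as a block and 2 residual degrees of freedom, 3 genes were higher and 1 lower in the knockout on water, and 2 and 2 in the knockout on serine. With the same block, 1 unannotated transcript was called on water and 0 on serine against control. The block ended the calls of the gluconeogenesis list on water (adjusted p = 0.0557) and of the mitochondrially encoded list with serine against water (adjusted p = 0.0581). With it the cholangiocyte list on water passed as lower (adjusted p = 0.0272).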

Other observations

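The lists in this part were fixed beforehand, while all tests of explanations below were chosen after the values were seen.

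Values of the lists below are given for the knockout on water against control on water, serine against water in knockouts and knockout on serine against control on water, in that order. Of the lists of cell types other than hepatocytes, only that of cholangiocytes and progenitors passed, in knockout on serine against control. Cholangiocyte and progenitor markers had a median of -0.87 on water (camera adjusted p = 0.0600), with Afp, alpha-fetoprotein, higher (1.05) and Sox9 lower (-1.51) adjusted over the list alone, and of 0.09 with serine (adjusted p = 0.667). On water it passed as lower without a filter (adjusted p = 0.00287). Kupffer cell and macrophage markers did not pass (adjusted p = 0.846, 0.667 and 0.802), although Cd14, a receptor for bacterial lipid, rose adjusted over the list alone (3.51). Stellate cell and matrix genes did not pass (adjusted p = 0.556, 0.415 and 0.0999), but did in the knockout on serine against control with median-of-ratios scaling (adjusted p = 0.0353), without a filter (adjusted p = 0.0243), without the variance trend (adjusted p = 0.0490), without control replicate 1 (adjusted p = 0.0120) or without knockout serine replicate 2 (adjusted p = 0.00649). Lymphocyte and neutrophil markers did not pass (adjusted p = 0.846, 0.302 and 0.340), except as lower on serine against control without control replicate 1 (adjusted p = 0.0438) or without a filter (adjusted p = 0.0243). Sinusoidal endothelial markers did not pass (adjusted p = 0.993, 0.950 and 0.985). Blood, pancreas and adipose markers did not pass (adjusted p = 0.551, 0.181 and 0.905), but were lower on water without knockout water replicate 2 (adjusted p = 0.00189).

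Pericentral hepatocyte markers did not pass (adjusted p = 0.846, 0.849 and 0.985), with Cyp2a5, a coumarin hydroxylase, higher adjusted over the list alone on water (1.29) and on serine against control (1.36). Periportal markers did not pass (adjusted p = 0.778, 0.667 and 0.658), yet Etnppl rose on water and on serine against control, and Aldh1b1, a mitochondrial aldehyde dehydrogenase, rose on serine (1.35), a call that ended with median-of-ratios scaling (adjusted p = 0.0700). Adjusted over the list alone, 6 periportal genes rose and 2 fell on water, among them Cdh1, E-cadherin (1.01), and Cyp2f2 (-1.08). Female-biased genes did not pass (adjusted p = 0.778, 0.181 and 0.121), and were lower on serine against control with TPM scaling (adjusted p = 0.0358). Hamp2 rose, and adjusted over the list alone Cyp2b10 rose (3.79) and Cyp17a1 fell (-3.52) on water. The p53 targets did not pass (adjusted p = 0.449, 0.182 and 0.0999), with the cell cycle inhibitor gene Cdkn1a lower on serine against control (-1.12). Cell cycle genes did not pass (adjusted p = 0.975, 0.684 and 0.802), and none of the 11 was called.

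Mitochondrial mRNAs shifted by unequal amounts. The ratio of mt-Nd1 to mt-Nd2 was 0.812 and 0.869 in controls, 1.82 and 1.99 in knockouts on water, and 1.99 and 2.19 on serine. A lower yield of mitochondrial RNA as a whole is argued against by the SD over the 13 mRNAs, 0.343 on water and 0.427 on serine, where replicate spread gives 0.154. For 5 of the 13, a nuclear insertion on chromosome 1 holds similar genes, and their levels are uncertain. Over the other 8 the SD was 0.396 on water and 0.446 on serine, where replicate spread gives 0.0966. Reads of mt-Nd2 lost to nuclear copies are argued against by a mean 2978 FPKM lower on water, where the 3 similar nuclear genes stood at 0. A mitochondrial sequence difference between the mouse lines could also produce such a ratio, and remains open because reads were not analysed here.

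Clock genes of the evening were higher in the knockouts and those of the opposite phase mostly lower. On water 9 of 10 evening genes and 4 of 5 opposite genes went that way, with medians of 0.95 and -0.55. A rise of all clock genes from scaling would shift both groups of genes alike. The opposite genes alone do not settle this: their median was -0.62 after median-of-ratios scaling (SE 0.353 over 5 genes), within 2 SE of 0, and Cry1 rose. The difference of 1.49 (SE 0.466) between the groups of genes argues against scaling as the only cause. That SE is over genes and does not measure spread between pools. The 2 control pools differed in a similar way. From control replicate 1 to replicate 2, Dbp went from 2.81 to 16.4 FPKM and Ciart from 1.8 to 4.8. Per1, Per2 and Usp2 were not higher there. All 5 opposite genes were lower in replicate 2, among them Cry1 (4.75 to 1.81 FPKM) and Nfil3 (22.8 to 15.4). Variation between pools was not tested and stays open as a cause. A later clock phase may explain the difference of 1.49 (SE 0.466) between the groups of genes, but collection times are not given in the sources used here, so phase and genotype cannot be told apart. On serine against control the evening median was 1.17 and the opposite one -0.06.

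Gm7336, a processed copy of Gapdh on chromosome 7, stood at 240 and 13.9 FPKM in controls, 0 and 2.47 in knockouts on water and 3.12 and 1.10 on serine. Gapdh reads assigned to this copy may account for its level, since 97.8% of its 1208 25-base words occur in Gapdh transcripts. The table held 257 Gapdh-like genes, most of them near 0, and 18 others had a mean of 0.1 FPKM or more. The median change of these 18 was -0.32 (SE 0.145), in the direction of a fall. At levels near 0.1 FPKM the pseudocount keeps any fall small. These 18 therefore cannot decide whether all such copies fell, and that explanation stays open. The difference between the 2 control libraries stays open.

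Gm43778, a gene model of 199 bases on chromosome 5, was listed at 0 in both controls and at 74.0 and 54.5 FPKM in knockouts on water. The metallothionein gene Mt1 stood at 667 and 682 FPKM in controls, 816 and 612 in knockouts on water and 113 and 292 on serine. Kiss1, which encodes kisspeptin, was listed at 0 in controls and on serine and at 2.32 and 4.67 FPKM in knockouts on water. Ldha, a lactate dehydrogenase subunit, stood at 1172 and 1232, then 443 and 665, then 664 and 471 FPKM, and Ldhb at 1.97 and 1.10, then 17.9 and 6.73, then 6.69 and 31.6 FPKM.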
